A study of Homo sapiens with 6 samples.

How the data were processed

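Expression was measured in Rh30 cells, a line grown from a human alveolar rhabdomyosarcoma that carries the PAX3-FOXO1 fusion. Per the labels, 3 samples received a control siRNA and 3 an siRNA directed against P/CAF, the acetyltransferase encoded by KAT2B, and total RNA was taken 72 h after transfection. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column, checked on a Bioanalyser, amplified to biotinylated cRNA and hybridised to Illumina HT-12 arrays of 1 colour. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of siRNA sequences used is not given in the sources used here.

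The deposited table of non-normalized values holds, for each of 47323 probes and each array, a bead signal as intensity on a linear scale, per the file headers, with no between-array normalization. The deposited table also holds a score beside each intensity, headed as a p value per the file headers. That score rises with the signal and lies near 1 for bright probes, so it was read as 1 minus the detection p, a reading taken from the values. The deposited series matrix holds values on a log2 scale, centred on each probe's median. Scale and centring are not stated and were found by setting each column against the same array's signals (r between 0.933 and 0.970, slopes between 0.850 and 1.07, over probes with a signal above 150 on all arrays). Direction followed from the positive slopes, and the median of each matrix column was 0. The normalization behind the matrix and the software behind both tables are not given in the sources used here. The matrix served as an alternative only.

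Signals were background-corrected by normexp with the detection p-values standing in for negative controls, an offset of 16 was added, and arrays were quantile normalized and log2 transformed (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 21232 probes. Median signals per array lay between 79.1 and 89.7, and between 20891 and 21421 probes were detected per array, of which the array total is 47323. No 2 arrays held identical values, and arrays of a group correlated at 0.981 to 0.994. The number of arrays limits the precision.

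Probes were named from the platform annotation. Of all probes, 30113 had 1 gene symbol, 8 had several and 17202 had none here; the last 2 kinds were not named. Of the annotated probes, 30074 matched a gene identifier of the reference gene table of assembly GRCh38.p14 (47 did not), and no symbol changed. The array tables used here name no genome build, so no coordinates are given. The 16098 tested probes with a symbol stood for 11806 genes, each represented by its tested probe of highest mean signal; where another tested probe of a named gene went another way or differed in its call, the text says so. Genomic spans (gene start to gene end) came from the reference gene table, for 99.9% of tested genes.

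The siP/CAF arrays were compared with the control siRNA arrays by limma (lmFit, eBayes) without a block. P-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. A gene not detected on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean against the mean, per array, of the higher of its own value and the lowest normalized value among detected probes. Error values are SD over 3 arrays per group, and log2 differences are siP/CAF minus control siRNA.

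The groups, the test, the alternatives, the rule for named genes and 29 gene lists with 970 genes were fixed before the data were examined. Of the listed genes, 745 were tested and 65 had no probe named here. The lists cover the study's themes (7 lists on proliferation, growth, apoptosis and muscle development), PAX3-FOXO1 targets, acetyltransferase complexes, interferon, stress and metabolic genes, and markers of other cell types. Genes named are KAT2B, KAT2A, EP300, CREBBP, PAX3, FOXO1, MYOD1 and MYOG; the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap; and in each list the 4 tested members with the smallest p. Other changed members of a list, the members of 6 lists added after the data were seen, and second probes were named after their values were seen. List shifts were tested with camera in limma at a preset correlation of 0.01, adjusted over the 29 lists, with camera at an estimated correlation and fry as alternatives. The 6 added lists were adjusted over those 6 alone. Members were also adjusted over the list alone.

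The procedure was tested on simulated data with 200 changed probes among 21232, 3 arrays against 3. It recovered 62% of 2-fold and 93% of 4-fold changes, with 3.12% false among the called, and found the 1 list that had been shifted, by -0.50 on the log2 scale, and 0 of the 28 others. That shift is larger than those reported and the simulated noise was independent between genes, so this says little of smaller shifts or of correlated genes.

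Alternatives were 4 other normalizations (no background correction, normexp with an offset of 50, median scaling, the series matrix), no filter, a detection p under 0.01 on all arrays, a trended robust prior, array weights, each array left out in turn, replicate blocks, the mean over a gene's probes, and an adjusted p under 0.01. Added after the data were seen were the fit without control array 3 and siP/CAF array 3 and a fit with the trend against genomic span removed. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9.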

Results

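Gene expression was profiled in Rh30 cells, a line from alveolar rhabdomyosarcoma, a childhood tumour of cells resembling skeletal muscle precursors in which the PAX3-FOXO1 (Pax3-FKHR) fusion protein acts as a transcription factor. The samples were 3 of cells given a control siRNA and 3 of cells given an siRNA against P/CAF (siP/CAF), a lysine acetyltransferase and coactivator encoded by KAT2B, each taken after 72 h. The design asked which genes of proliferation, growth, apoptosis and muscle development depend on P/CAF. Each sample was read on 1 Illumina bead array with 47323 probes. Between 20891 and 21421 probes per array were detected, the brightest signals per array lay between 37287 and 45338, and 11806 named genes were tested.

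The siRNA lowered its target. KAT2B (probe ILMN_3243142) measured 9.49 ± 0.36 on the log2 scale (SD, n = 3) in control cells and 6.72 ± 0.29 (SD, n = 3) in siP/CAF cells, a 6.83-fold fall. The log2 difference was -2.77 with an SE of 0.22 (limma with Benjamini-Hochberg adjustment, adjusted p = 1.91e-04). The background-uncorrected signals were 749, 608 and 1093 in the controls and 178, 172 and 136 after siP/CAF. A second KAT2B probe was near background, detected on 2 control arrays and on 0 siP/CAF arrays, and was not tested. The closest paralog, KAT2A, measured 0.24 and did not pass. The acetyltransferases EP300 (-0.40) and CREBBP (-0.39) also did not pass, although a dimmer CREBBP probe fell by 0.91 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0259).

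**Figure D1:**
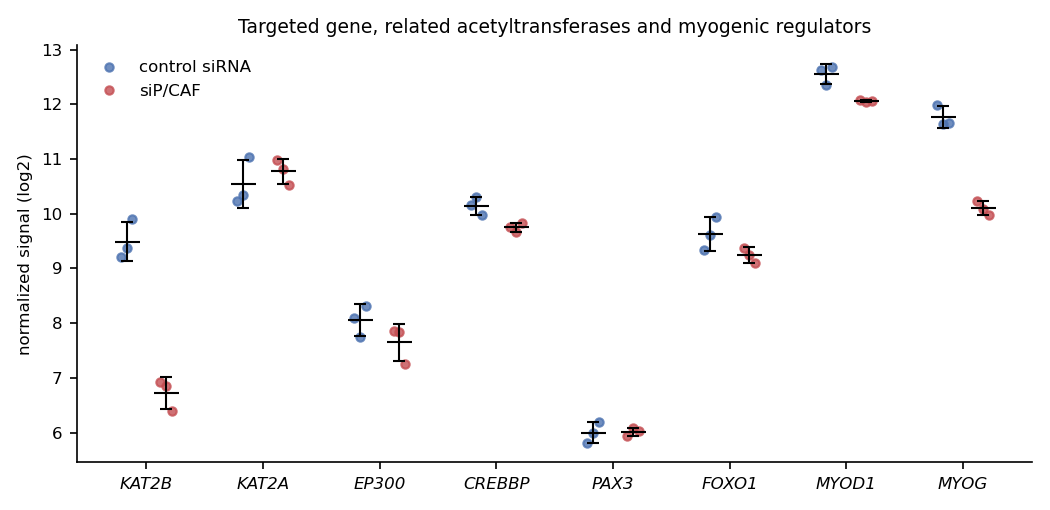
Normalized signal (log2, vertical axis) of KAT2B, related acetyltransferases and myogenic regulators in the 3 control siRNA arrays (blue) and 3 siP/CAF arrays (red); points are arrays, bars the mean and SD. KAT2B and MYOG passed the test, with log2 differences of -2.77 and -1.67, and the others did not pass.

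The largest changes after siP/CAF included rises of TAGLN, ACTG2, MEOX1 and CXCL8 and falls of FOXS1, GLI1 and MYLK2. TAGLN, which encodes the actin-binding protein transgelin, rose from 9.41 ± 0.39 to 12.32 ± 0.05 on the log2 scale (SD, n = 3), a log2 difference of 2.91. ACTG2, the enteric smooth-muscle actin, rose by 2.54, and MEOX1, a homeobox gene of the somite, rose by 2.53. The chemokine CXCL8 (interleukin 8) rose by 2.45, the vasoconstrictor peptide gene EDN1 by 2.24 and EBI3, a subunit of heterodimeric cytokines, by 2.21. A dimmer CXCL8 probe rose less, by 1.34. A dimmer MEOX1 probe also rose, but no control array detected it, so its rise has only a lower limit. MYOG, which encodes myogenin and drives terminal muscle differentiation, fell by 1.67 on the log2 scale, from 11.76 ± 0.20 to 10.10 ± 0.13 (SD, n = 3).

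Some of the largest rises started below detection in every control array, so that only a lower limit can be given. Such limits, for rises and falls, hold under the background correction used. SAA1, an acute-phase apolipoprotein, was at least 5.69-fold higher after siP/CAF, and its probe may also read the near-identical SAA2. The matrix metalloproteinase gene MMP9 was at least 3.38-fold higher, the complement regulator C4BPB at least 3.21-fold on its brightest probe, the neuropeptide gene KISS1 at least 3.17-fold and the receptor phosphatase PTPRZ1 at least 3.08-fold. A dimmer C4BPB probe, also below detection in every control array, rose as well, and the sizes on these probes cannot be ranked. HSD52 rose by 2.03 on the log2 scale. After KAT2B itself, the deepest falls under the background correction used were of FOXS1 (-2.58), a forkhead transcription factor, SOHLH1 (-2.50), a germ-cell transcription factor, and GRIN1 (-2.36), a glutamate receptor subunit. SOHLH1 and GRIN1 were detected on 1 of the 3 siP/CAF arrays each, so the size and rank of their falls are uncertain. MYLK2, the skeletal muscle myosin light chain kinase, fell by 2.19, GLI1, the transcription factor at the end of Hedgehog signalling, by 2.09 and the retinoic acid synthesising enzyme ALDH1A3 by 2.02. OLFM1 was below detection on all siP/CAF arrays and at least 3.62-fold lower there. AGXT (-1.94), the microfibril gene MFAP4 (-1.82), LEFTY1 (-1.78, a near-identical copy of LEFTY2) and FBXO2 (-1.75) completed the 12 largest falls. Sizes at dim probes, and so the order of the changes, depended on the background correction. Without it ACTG2 measured 1.67, MEOX1 1.54, SAA1 1.76, MMP9 1.37, OLFM1 -1.18, SOHLH1 -1.49 and GRIN1 -1.39, all still called, while TAGLN, a bright probe, measured 2.80. The 24 genes with the largest changes had limma adjusted p-values (Benjamini-Hochberg) between 6.59e-05 and 0.00252.

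**Figure D2:**
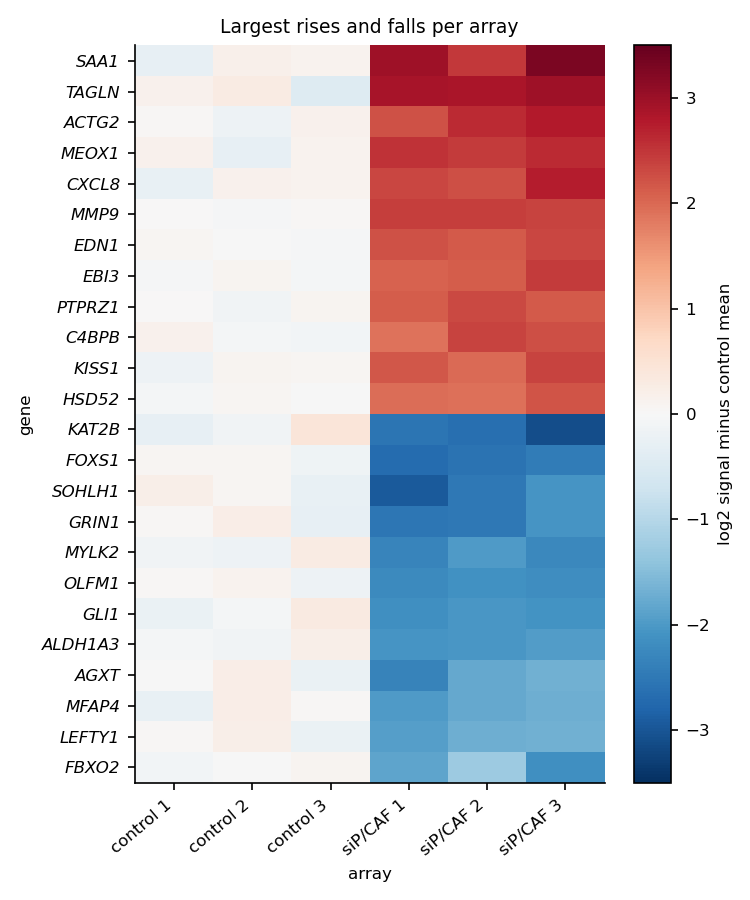
Log2 signal of the 12 largest rises and 12 largest falls (vertical axis) on each of the 6 arrays (horizontal axis), coloured by the difference from the control mean (red higher, blue lower, log2). The 3 siP/CAF arrays lie on one side of the 3 control arrays for each of the 24 genes.

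In all, 634 of 11806 genes changed (5.37%; limma, Benjamini-Hochberg adjusted p under the threshold of 0.05), 269 of them higher and 365 lower after siP/CAF. Among them 631 changed at least 1.5-fold and 228 at least 2-fold, 107 higher and 121 lower. Without adjustment, 2428 genes had a p under 0.05. The groups did not overlap for 27.7% of tested genes. For exchangeable arrays the average over splits is 10%, but genes that vary together can put a single split far from it. The share was not computed for other splits. Counted as probes, 972 changed, 438 higher and 534 lower, and 142 of these carried no gene symbol here. The median over all genes was -0.01. The count depended on single arrays. It was 209 genes without siP/CAF array 1, 240 without control array 1, 267 without siP/CAF array 2, 335 without siP/CAF array 3, 356 without control array 2 and 703 without control array 3, and 1748 with array weights.

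**Figure D3:**
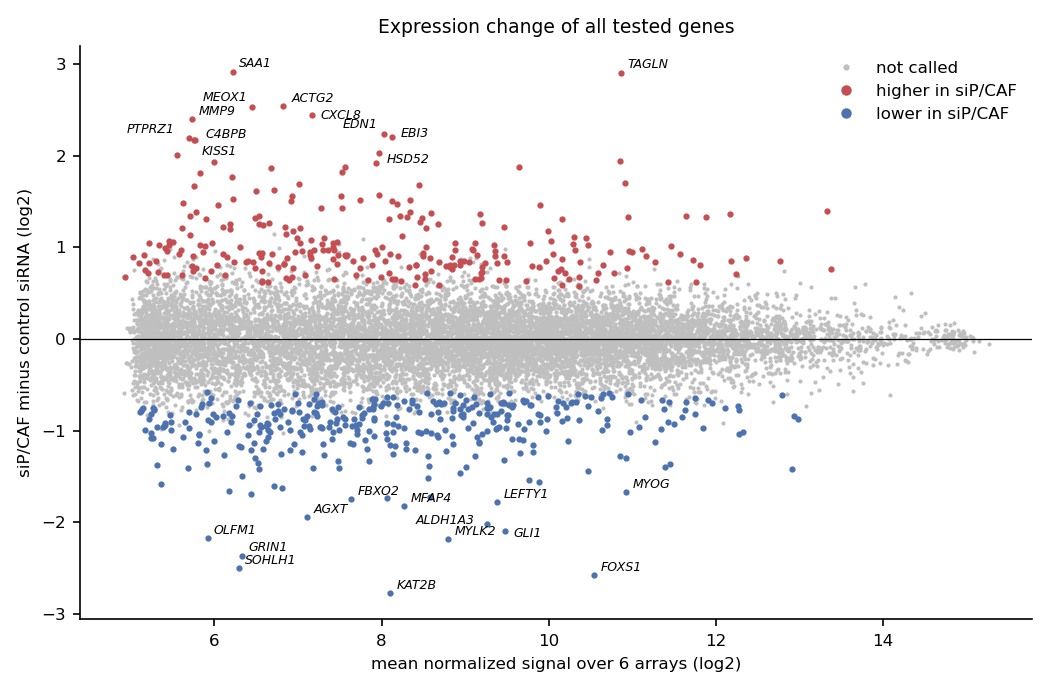
Log2 difference between siP/CAF and control siRNA (vertical axis) against the mean normalized log2 signal over 6 arrays (horizontal axis) for 11806 genes; red, 269 genes higher; blue, 365 lower; grey, not called. Genes below detection in one group, such as SAA1 and OLFM1, are drawn at their fitted difference, for which the text gives a lower limit.

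Genes of DNA replication lay slightly lower after siP/CAF. Of 46 measured members, 3 fell and none rose on their brightest probes: CHAF1A, a histone chaperone subunit of replicating chromatin (-1.03), E2F2, an activating transcription factor of S phase (-0.98), and the flap endonuclease FEN1 (-0.61). The nucleotide hydrolase DUT measured -0.54, and a dimmer DUT probe 0.18. On dimmer probes RFC3 rose by 1.28, against -0.13 on its brightest, and FEN1 measured -0.56 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0148 and 0.0841). Adjusted over the list alone, 7 members fell. The replication list had a median of -0.16 (camera in limma, Benjamini-Hochberg adjusted p = 0.00378; adjusted p = 0.645 with an estimated correlation). On control array 3 its members lay 0.14 above the control mean, and without that array the median was -0.13. FEN1 lost its call when any 1 array was left out and E2F2 without siP/CAF array 1 or 3 (limma, Benjamini-Hochberg adjusted p up to 0.205 and 0.0808, both without siP/CAF array 1).

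Mitotic genes showed no list shift. INCENP, a subunit of the chromosomal passenger complex, fell by 0.77 and was the 1 of 51 members to change; its call was lost without any 1 array, and a dimmer INCENP probe measured -0.27 and did not pass. FOXM1 (-0.56), KIF11 (-0.40) and KIFC1 (-0.42) did not pass, the list's median was -0.06 (camera in limma, Benjamini-Hochberg adjusted p = 0.377), and none passed when adjusted over the list alone, with 7 at an unadjusted p under 0.05 in limma. Among 19 inhibitors of the cell cycle 3 rose and none fell, with 4 called when adjusted over the list alone, 3 of them higher. They were the stress-induced GADD45B (1.22), the CDK4 inhibitor gene CDKN2B (1.12) and BTG1 (0.62); BTG1 lost its call without any 1 array. A dimmer probe of CCNG2, another member, fell by 1.18, against -0.28 on its brightest. CDKN1A, the p53-induced inhibitor p21, measured -0.58 (limma, Benjamini-Hochberg adjusted p = 0.0523). The inhibitors' median was -0.01 while their mean (0.10) and camera's direction were above 0 (camera in limma, Benjamini-Hochberg adjusted p = 0.535). Of 25 p53 targets 1 rose, the kinase gene PLK2 (0.91), GDF15 measured -0.80 and PMAIP1 0.45, and 3 passed when adjusted over the list alone. The p53 list's median was -0.01 (camera in limma, Benjamini-Hochberg adjusted p = 0.996), and PLK2 lost its call without control array 1 or 2 or siP/CAF array 1 or 2.

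Growth factor signalling genes moved both ways. Of 39 measured members 2 rose and 2 fell. IGFBP6, a binding protein that sequesters IGF2, rose by 1.36 and the receptor gene PDGFRB by 1.04, while IGF2, the growth factor abundant in this tumour type, fell by 0.71 and IGFBP2 by 0.72. Adjusted over the list alone, 13 members passed, 4 higher and 9 lower. CCND2 measured -0.61 and did not pass, while a dimmer CCND2 probe fell by 0.82. As a whole the list had a median of -0.03 (camera in limma, Benjamini-Hochberg adjusted p = 0.573). PDGFRB, IGF2 and IGFBP2 lost their calls without each array except control array 3 (limma, Benjamini-Hochberg adjusted p up to 0.0881, 0.169 and 0.158, each without siP/CAF array 1), and IGFBP6 without control array 1 (0.0718).

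Among 33 genes that promote apoptosis 2 rose and none fell, and the same number passed when adjusted over the list alone. BAK1, a pore-forming protein of the mitochondrial outer membrane, rose by 1.18 and the inflammatory caspase gene CASP4 by 0.87; a dimmer CASP4 probe measured 0.46. BNIP3L measured 0.24 and did not pass, while a dimmer BNIP3L probe rose by 0.71. CYCS measured -0.58 and PMAIP1 0.45. The promoting list had a median of 0.04 (camera in limma, Benjamini-Hochberg adjusted p = 0.470). Of 16 genes that restrain apoptosis none passed limma's test over all probes, 4 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone, 2 higher and 1 lower. BAG4 measured 0.67, BCL2 -0.69, TNFAIP3 0.58 and BIRC5 (survivin) -0.48, and the list's median was 0.09 (camera in limma, Benjamini-Hochberg adjusted p = 0.573). CASP4 passed without control array 3 and lost its call without each other array, and BAK1 lost it without control array 1, siP/CAF array 1 or siP/CAF array 2 (limma, Benjamini-Hochberg adjusted p up to 0.0738 and 0.0830).

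Regulators of muscle development lay lower after siP/CAF. Of 45 measured members 5 fell and 1 rose. Beside MYOG, the falls were of HDAC4 (-1.14), a deacetylase that represses MEF2 factors, TCF3 (-1.10), the E-protein partner of MYOD1, the Notch target HES1 (-1.04) and the bHLH repressor MSC (-0.70), and the rise was of MEOX1. HDAC4, HES1 and MSC restrain myogenesis, whereas MYOG and TCF3 promote it. MYOD1 itself, at 12.55 ± 0.18 and 12.06 ± 0.01 (SD, n = 3), differed by -0.50 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.102). KLHL41 measured -0.58 and did not pass, while a dimmer KLHL41 probe fell by 0.71. Adjusted over the list alone, 15 members passed, 14 of them lower. Over all 45 members the median was -0.29 (camera in limma, Benjamini-Hochberg adjusted p = 1.23e-04; adjusted p = 0.595 with an estimated correlation). On control array 3 the members lay 0.12 above the control mean, and the median without that array was -0.24. HES1 and MSC lost their calls without each array except control array 3 (limma, Benjamini-Hochberg adjusted p up to 0.0879 and 0.131).

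Contractile and sarcomere genes split. TNNI1, slow skeletal troponin I, fell by 1.23, while the tropomyosin genes TPM1 and TPM2, which also serve the actin cytoskeleton of other cells, rose by 0.86 and 0.76 and the sarcoglycan gene SGCA by 0.96. These 4 were the changed genes among 34 measured, and 8 passed when adjusted over the list alone, 3 higher and 5 lower. Contractile genes had a median of -0.12 (camera in limma, Benjamini-Hochberg adjusted p = 0.613). Dimmer TPM2 probes measured 0.74 and 0.17 and did not pass. TPM2 lost its call without each array except control array 3, SGCA without control array 1 or any siP/CAF array, and TPM1 without siP/CAF array 1 or 2 (limma, Benjamini-Hochberg adjusted p up to 0.0916, 0.101 and 0.0780).

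Genes reported as targets of the PAX3-FOXO1 fusion lay lower as a group. Of 26 measured, 4 fell: MYOG, the GABA transaminase ABAT (-1.39), the arginine synthesis enzyme ASS1 (-1.36) and PIPOX (-1.01). The BMP antagonist GREM1 rose by 1.31. Adjusted over the list alone, 14 passed, 13 of them lower. The targets had a median of -0.45 (camera in limma, Benjamini-Hochberg adjusted p = 5.07e-04; adjusted p = 0.604 with an estimated correlation), with members 0.08 above the control mean on control array 3 and a median of -0.33 without that array. A dim ABAT probe measured -0.01, and ASS1 lost its call without control array 1 (limma, Benjamini-Hochberg adjusted p = 0.0509). The genes joined in the fusion did not change by this test: PAX3 measured 0.02 on its brighter probe and -0.19 on another, both dim, and FOXO1 -0.39. None of these probes was checked for whether it reads the fusion transcript.

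In the enzymes of lysine acetylation, KAT2B and HDAC4 fell, HDAC11 measured -0.64 and HDAC9 0.79; these 2 falls were the changes among 32 measured members, and 5 passed when adjusted over the list alone. That list's median was -0.12 (camera in limma, Benjamini-Hochberg adjusted p = 0.0634), and it was called lower without control array 2 or siP/CAF array 2 (adjusted p = 0.0129 and 0.0296). KAT2B, the target of the siRNA, is a member of this list and of the next, so part of each camera result follows from the silencing itself. Neither list was tested without KAT2B. Of 26 subunits of the SAGA and ATAC complexes, in which P/CAF acts, 3 fell, also when adjusted over the list alone: KAT2B, the adaptor TADA2B (-0.85) and WDR5 (-0.60). TADA3 measured -0.42 and a dimmer WDR5 probe -0.05. The complexes' median was -0.10 (camera in limma, Benjamini-Hochberg adjusted p = 0.168), and WDR5 lost its call without any 1 array and TADA2B without control array 1, siP/CAF array 1 or siP/CAF array 3.

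Interferon response genes lay slightly higher, with no single member passing on its brightest probe. On 2 dimmer probes IFIT3 rose by 0.83 and 0.80 (limma, Benjamini-Hochberg adjusted p = 0.0143 and 0.0186). IFIH1 measured 0.68, IFIT3 on its brightest probe 0.61, RIGI 0.53 and IFIT1 0.47. Of 33 measured, each by its brightest probe, none passed limma's test, 10 had an unadjusted p under 0.05 and 2 passed when adjusted over the list alone, both higher. Interferon genes had a median of 0.19 (camera in limma, Benjamini-Hochberg adjusted p = 0.0144; adjusted p = 0.595 with an estimated correlation). This shift was not called without control array 1, control array 3 or siP/CAF array 3 (camera in limma, Benjamini-Hochberg adjusted p up to 0.0857). Of 13 genes of small-RNA silencing, including DICER1 (0.33), AGO1 (0.25), TNRC6A (0.23, and -0.47 on a dimmer probe) and TNRC6C (-0.47), none passed over all probes or over the list alone, with 0 at an unadjusted p under 0.05 in limma, and the median was -0.01 (camera in limma, Benjamini-Hochberg adjusted p = 0.996).

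Matrix and immediate-early genes held more single changes than list shifts. Of 35 extracellular matrix and mesenchymal genes 5 rose and none fell: the collagen cross-linking enzyme LOX (1.92), the matricellular genes CCN1 (1.40), CCN2 (1.11) and THBS1 (0.72), and the protease inhibitor TIMP3 (0.95). Adjusted over the list alone, 12 passed, 7 higher and 5 lower, and the median was 0.01 (camera in limma, Benjamini-Hochberg adjusted p = 0.602). Of 24 immediate-early genes 3 rose, the MAP kinase phosphatases DUSP1 (1.33) and DUSP5 (0.77) and IER2 (0.65), and 3 fell, the AP-1 subunits JUND (-0.87) and FOS (-0.60) and the receptor signalling inhibitor SPRY4 (-0.64; -0.46 and not passing on a dimmer probe). Of these 12 passed when adjusted over the list alone, 7 higher, and the median was 0.09 (camera in limma, Benjamini-Hochberg adjusted p = 0.470). FOS and SPRY4 lost their calls without any 1 array, IER2, DUSP5 and THBS1 without each except control array 3, JUND without control array 1 or siP/CAF array 1, and TIMP3 without siP/CAF array 1.

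Stress and metabolic lists were not called in the fit reported. ADM, a vasodilator peptide gene induced by hypoxia, rose by 1.68 and the collagen prolyl hydroxylase P4HA2 fell by 0.97, the 2 changes among 32 glycolysis and hypoxia genes, also when adjusted over the list alone; PDK1 measured -0.54 and ENO2 0.46 (median 0.10; camera in limma, Benjamini-Hochberg adjusted p = 0.103; called in 3 of 22 alternatives). In the unfolded protein response 1 of 30 genes fell, DDIT4 (-0.72), also over the list alone, with SLC7A5 at -0.61, DNAJB9 at 0.44 and PHGDH at -0.48 (median -0.04; camera in limma, Benjamini-Hochberg adjusted p = 0.602). Of 16 heat shock genes 1 fell, HSPA1B (-0.67), whose probe may also read the near-identical HSPA1A, and DNAJB1 measured -0.41, HSPB8 0.36 and DNAJB4 0.38 (median -0.03; camera in limma, Benjamini-Hochberg adjusted p = 0.613). In cholesterol synthesis the sterol monooxygenase MSMO1 rose by 0.85 as the 1 change among 23, a dimmer MSMO1 probe measured 0.24 and did not pass, MVK measured 0.56, LSS -0.39 and HMGCS1 0.35, and 2 passed when adjusted over the list alone (median 0.06; camera in limma, Benjamini-Hochberg adjusted p = 0.470). Among 30 lysosome and autophagy genes SCARB2 fell by 0.70 and HEXA rose by 0.68, also over the list alone; OPTN measured 0.48, CTSL 0.39 and CTSB -0.06, with a dimmer CTSB probe lower by 0.65 (median 0.09; camera in limma, Benjamini-Hochberg adjusted p = 0.168). HSPA1B lost its call without any 1 array, DDIT4, SCARB2 and HEXA without each except control array 3, and MSMO1 without siP/CAF array 1 or 2.

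No member of 4 further lists passed limma's test over all probes or over the list alone. These were 45 oxidative phosphorylation genes (1 at an unadjusted p under 0.05; CYCS -0.58, NDUFB7 -0.54, COX7B -0.37, SDHA -0.33), 42 cytosolic ribosomal proteins (2 at an unadjusted p under 0.05; RPL29 0.74, RPS7 0.63, RPS23 -0.34, RPL35 0.32), 30 ribosome biogenesis genes (0 at an unadjusted p under 0.05; NOP2 0.31, PES1 0.32, NOLC1 0.30, RRP12 -0.26) and 12 replication-dependent histones (3 at an unadjusted p under 0.05; H4C8 -0.58, H2BC21 -0.54, H2BC4 -0.48, H2AC11 0.35). Their medians were -0.05, 0.03, 0.00 and -0.07 (camera in limma, Benjamini-Hochberg adjusted p = 0.589, 0.425, 0.613 and 0.573). Oxidative phosphorylation and histone genes lay 0.30 and 0.29 below the control mean on control array 3. Without that array the oxidative phosphorylation list lay lower (median -0.18; camera in limma, Benjamini-Hochberg adjusted p = 0.0105).

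Few markers of other cell types were measurable, and they went both ways. KRT7, a keratin of simple epithelia, rose by 1.57 as the 1 change among 4 epithelial markers (ELF3 0.47, CLDN4 0.12, KRT8 0.04); on control array 3 these 4 lay 0.41 below the control mean and on siP/CAF array 3 they lay 0.32 above the siP/CAF mean. The lysozyme gene LYZ, below detection in every control array, was at least 1.30-fold higher, the 1 change among 6 blood cell markers (CD14 0.34, CD68 0.20, CORO1A 0.11). SOX2, a transcription factor of neural and stem cells, was below detection on all siP/CAF arrays and at least 1.80-fold lower, and DCX measured -0.46, TUBB3 -0.44 and MAP2 0.08. A second SOX2 probe measured -0.56 and did not pass. The neural median was -0.45 over 4 genes, with 3 passing over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0245; adjusted p = 0.595 with an estimated correlation), and this shift was not called without control array 1. PECAM1, an endothelial adhesion molecule, fell by 0.59 as the 1 change among 3 endothelial and adipose markers (CEBPA -0.31, LEP 0.25). The epithelial, blood and endothelial lists did not shift by camera in limma (medians 0.30, 0.15 and -0.31; Benjamini-Hochberg adjusted p = 0.168, 0.168 and 0.470), and in each of them 1 member passed over the list alone. KRT7 lost its call without control array 1, PECAM1 without each array except control array 3, and LYZ without control array 1 or any siP/CAF array, and also without background correction (0.37; limma, Benjamini-Hochberg adjusted p = 0.0829).

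**Figure D4:**
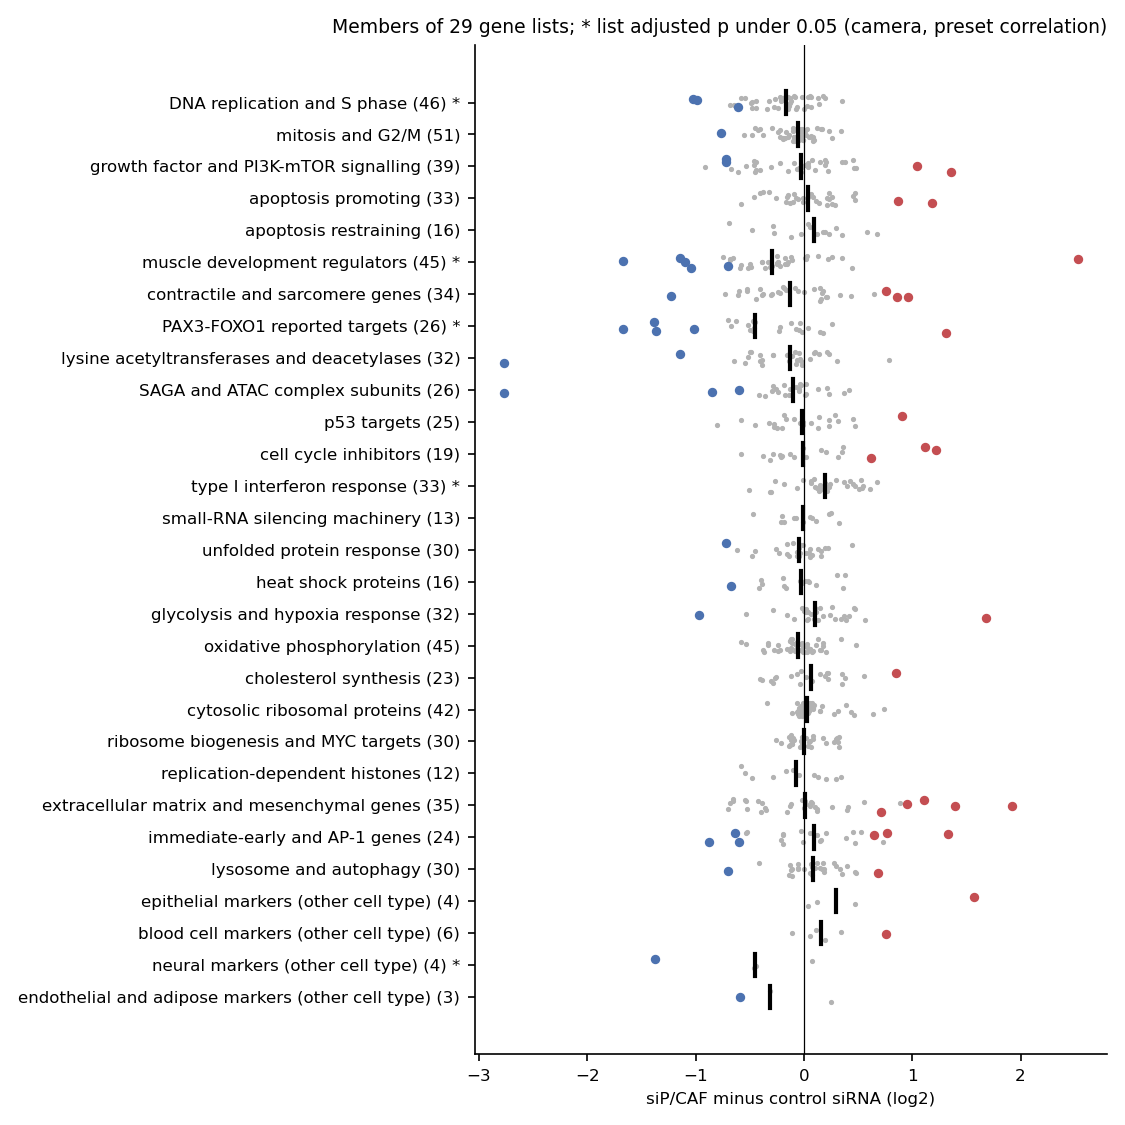
Log2 difference between siP/CAF and control siRNA (horizontal axis) of each tested member of 29 gene lists (vertical axis, with the number tested); red and blue points are members that rose or fell, grey points did not pass, black bars are list medians. The 5 lists with a star passed camera at the preset correlation, and none passed with an estimated correlation.

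Across the 29 lists, camera in limma called 5 at the preset correlation, fry called 1 (the neural markers) and none passed with an estimated correlation, where 1 had an unadjusted p under 0.05. Of the 9 other splits of the 6 arrays into 3 and 3, 2 called as many lists, the highest 7. Of the 53 genes of these lists that changed, 19 kept their call without each array in turn: KAT2B, MYOG, MEOX1, HDAC4, TCF3, TNNI1, ABAT, PIPOX, GREM1, CHAF1A, GADD45B, CDKN2B, ADM, P4HA2, LOX, CCN1, CCN2, DUSP1 and SOX2. By contrast 7 lost it whichever array was left out: BTG1, FEN1, FOS, HSPA1B, INCENP, SPRY4 and WDR5. Calls lost were 30 without control array 1, 22 without control array 2, 7 without control array 3, 31 without siP/CAF array 1, 27 without siP/CAF array 2 and 25 without siP/CAF array 3. List medians were the same with undetected genes set at their bounds.

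Arrays of one group differed along an axis led by control array 3, which held 59.6% of the within-group variance over genes. On that array genes of short genomic span lay low and genes of long span lay high. The tenth of genes with the shortest span (median 2.10 kb) lay 0.19 below the control mean on control array 3, and the tenth with the longest (median 235 kb) lay 0.17 above it. Control array 2 and siP/CAF array 3 deviated the other way. Deviations from a group mean balance out within the group, so an opposite deviation among the other control arrays was fixed by that of control array 3. The difference between the groups followed span weakly, with a Spearman rho of -0.08 across genes, which are not independent replicates.

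**Figure D5:**
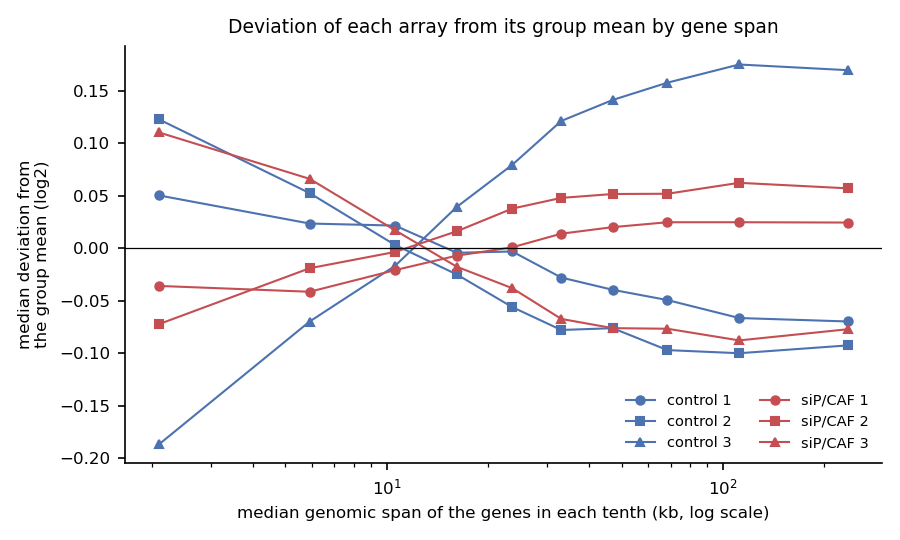
Median deviation of each array from its group mean (log2, vertical axis) for the tested genes ordered by genomic span in 10 equal parts (median span in kb, logarithmic horizontal axis); blue, 3 control siRNA arrays; red, 3 siP/CAF arrays. Control array 3 runs from -0.19 to 0.17, and control array 2 and siP/CAF array 3 slope the other way. Deviations balance out within a group, so the slopes of the control arrays are not independent.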

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

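The fits without control array 3 and siP/CAF array 3 and with the span trend removed were chosen only after the data were seen. The fall of KAT2B was called in all 20 alternatives that give it, with log2 differences from -2.91 to -2.25 and limma adjusted p-values (Benjamini-Hochberg) up to 0.00672. Of 1745 values of named genes and lists called neither in the fit reported nor in the alternative set against it, 49 had another sign. Another 113 values of named genes did not pass in the fit reported but were called in an alternative, and 193 lost their call. Without background correction MYOD1 and CDKN1A were called (limma, Benjamini-Hochberg adjusted p = 0.0455 and 0.0162). Of 20 alternatives, MYOD1 stayed uncalled in 16 and CDKN1A in 10, and each was called lower in the rest. The 4 other normalizations called 721 to 802 genes and shared 555 to 570 of the 634. No background correction, normexp with an offset of 50 and the series matrix were near-duplicates (802, 801 and 796 genes). Calls were 42.4% higher in the fit reported, and 34.7% to 41.7% in the 4 other normalizations. Median scaling, which moved the median of all genes to -0.06, called 8 lists. Weights gave control array 3 0.29 and siP/CAF array 1 2.67, and with them 1748 genes changed, 846 higher and 902 lower, 1118 at least 1.5-fold. At an adjusted p under 0.01, 176 changed (91 higher, 85 lower, 176 at least 1.5-fold). Leaving out 1 array at a time gave 209 (without siP/CAF array 1) to 703 (without control array 3) genes, 111 to 342 higher, 98 to 361 lower, 209 to 703 at least 1.5-fold, and 3 to 6 lists; fewer arrays lowered the count except without control array 3. Without control array 3 and siP/CAF array 3 together, 764 changed. With the span trend removed, 1009 changed, 466 higher, against 808 for the same genes untreated. Both fits left out probes without a genomic span, among them the 5134 tested probes with no symbol. The 808, against 634 in the fit reported, thus reflects the smaller set of probes. Apart from the fewer arrays and this smaller set, the cause of these differences was not tested.

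The DNA replication shift (-0.16) and the muscle regulator shift (-0.29) were not called by camera with an estimated correlation (adjusted p = 0.645 and 0.595) or by fry (0.0947 and 0.0534), and were called under the other 20 alternatives of each (over all 22, adjusted p from 1.06e-04 to 0.645 and from 7.93e-06 to 0.595). With an estimated correlation 0 lists were called (1 at an unadjusted p under 0.05), by fry 1 (11 at an unadjusted p under 0.05). The PAX3-FOXO1 target shift behaved alike (0.604 and 0.0534), while the interferon and neural shifts were each lost in 7 of 22 alternatives. Some lists not called in the fit reported were called in alternatives, of 22 each: lysine acetyltransferases and deacetylases in 7 (adjusted p down to 0.0129), oxidative phosphorylation in 4, glycolysis and hypoxia in 3, histones in 2, and ribosomal proteins and epithelial markers in 1 each, the last 2 under median scaling. The acetyltransferase list holds KAT2B, the target of the siRNA, and was not tested without it.

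Titles give the numbers 1 and 2 to a sample of each group, but whether they pair the samples is not stated. Deviations of same-numbered arrays correlated at -0.15 and -0.41, values that the axis led by control array 3 also shapes, so no pair was assumed. A fixed replicate block on those 4 arrays called 442 genes (genes lower, 213) against 764 on the same arrays without it. A random replicate block on 6 arrays (correlation -0.60) called 218, 103 higher and 115 lower, 218 at least 1.5-fold. A slide block was not run, as the files used here name no slide. Dim probes limit what can be said of genes near background, where 23 rises and 20 falls have only a bound.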

Other observations

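The 6 gene lists used here, the test of the axis against genomic span and the counts over splits of the arrays for genes were chosen only after the results were seen. The other tests had their criteria written first. Bootstrap intervals below resample genes, not arrays. Genes are not independent replicates, so these intervals do not measure the spread between samples.

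Inflammatory genes under NF-kappaB control lay higher after siP/CAF. Of 27 measured, 11 rose and none fell: beside SAA1, CXCL8, MMP9 and EBI3 these were the adaptor TRAF1 (1.82), the inflammasome genes NLRP3 (at least 2.67-fold) and CASP1 (1.32), IRAK2 (1.34), TNFRSF9 (1.21) and the NF-kappaB subunits RELB (0.97) and NFKB2 (0.59). NFKB2 lost its call without each array except control array 3, CASP1 without control array 1 or siP/CAF array 2 or 3, and TNFRSF9 without control array 1. Dimmer probes of TRAF1 (0.67) and NFKB2 (0.58) did not pass. The list's median was 0.57 (camera in limma, adjusted p = 0.00412 with an estimated correlation). Without the members among the 60 largest rises and 60 largest falls, from which it was noticed, 19 remained with a median of 0.41 (camera in limma, Benjamini-Hochberg adjusted p = 2.25e-06 at the preset correlation and 0.0315 with an estimated one). Of 21 genes known as targets of YAP and TEAD 9 rose and none fell, among them TGFB2 (1.52), CCN1 (1.40), NT5E (1.32), CRIM1 (1.28) and F3, the tissue factor gene (1.27). Among the other rises, NUAK2 lost its call without control array 1 or siP/CAF array 1 or 2. MYOF lost it without control array 1 or 2 or siP/CAF array 1 or 2. The 21 targets had a median of 0.48, and 0.33 over 18 genes outside the noticed ones (camera in limma, adjusted p = 0.0837 and 0.126 with an estimated correlation, 5.01e-08 and 5.61e-05 at the preset one). Leaving out members of the 29 fixed lists too gave medians of 0.16 over 15 YAP and TEAD targets and 0.40 over 16 NF-kappaB genes. Camera in limma with an estimated correlation gave adjusted p = 0.271 and 0.0457 for these.

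Hedgehog pathway genes lay lower after siP/CAF. Of 13 measured, 7 fell and none rose: FOXS1, GLI1, the feedback inhibitors HHIP (-1.32) and PTCH1 (-0.82), GLI2 (-0.96), the target FOXF1 (-1.11) and DISP1 (-0.78), which releases the ligand. DISP1 lost its call without any 1 array, PTCH1 and GLI2 without control array 1 or any siP/CAF array, and FOXF1 without control array 1 or 3 or siP/CAF array 1 or 3. SMO (-0.33), GAS1 (-0.38) and BOC (0.02) did not pass. The median was -0.78 (camera in limma, adjusted p = 0.0463 with an estimated correlation), and -0.35 over 10 genes outside the noticed ones (camera in limma, adjusted p = 3.45e-04 at the preset correlation and 0.126 with an estimated one). On control array 3 those 10 lay 0.19 above the control mean.

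Arrays of one group differed along 1 axis led by control array 3 (coordinate 0.68, against -0.44 for control array 2 and -0.43 for siP/CAF array 3). The first axis, computed anew under each of 4 other normalizations, held at least 0.599 of the within-group variance, against 0.596 here. That share met the criterion set against normalization as the source. Whether the first axis was the same one each time was not checked, so the share alone cannot decide this. No background correction, normexp with an offset of 50 and the series matrix gave nearly the same share (0.673 each), so they are not separate checks. A difference in RNA quality or in the length of transcripts captured is a candidate explanation: across genes the axis score followed genomic span with a Spearman rho of 0.369 (95% bootstrap interval 0.353 to 0.384). Genomic span measures neither RNA quality nor transcript length, so this value cannot show that either applies. The 500 genes lowest on control array 3 had a median span of 8735 bp and the 500 highest 47165 bp. No biological explanation was tested, and culture state stays open.

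Muscle development regulators and PAX3-FOXO1 targets lay lower after siP/CAF, with a shared median 0.28 below that of all genes. Both lists passed camera in limma at the preset correlation only, and neither passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.595 and 0.604) or by fry (0.0534 each), so the shift itself is not secure. Removing the trend with genomic span left -0.26 (95% bootstrap interval -0.42 to -0.18), and leaving out control array 3 left -0.25, between -0.30 and -0.25 over single arrays left out. These values argue against a trend with genomic span or 1 deviating array as the whole cause. The groups differed with span only weakly (Spearman rho -0.08), and span is not a measure of RNA quality. A difference in RNA quality that does not follow span was not tested. Off-target silencing by the siRNA stays open and cannot be told apart from loss of P/CAF, because there was 1 siRNA condition against the gene. Loss of P/CAF as a coactivator of these genes is a hypothesis that remains with it.

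Smooth-muscle actin and actin cytoskeleton genes lay higher after siP/CAF, with 7 of 29 called, all higher, among them ACTA2 (1.87), CNN1 (0.93) and TGFB1I1 (0.90), and a median of 0.43 (camera in limma, adjusted p = 0.0463 with an estimated correlation). CNN1 lost its call without control array 2 or any siP/CAF array, and TGFB1I1 without siP/CAF array 1 or 2. Admixed fibroblasts or smooth muscle cells are argued against: 34 of their restricted transcripts that were dim in controls had a median of -0.0055 (95% bootstrap interval -0.08 to 0.12), and 20 were undetected on all siP/CAF arrays, COL1A2 included. Of the 11 that passed the detection filter 2 rose (PDGFRB and CNN1), so the count of rises adds little. The tested members of the fibroblast (12) and smooth-muscle (5) lists had medians of -0.11 and -0.15. Each was detected on all 3 control arrays, and COL3A1, THY1, SFRP1, LOXL1, DES and SYNM were not dim there. The medians of these tested members therefore cannot decide whether other cells were admixed. Removing the span trend left the actin set's shift at 0.44, against 0.44 before. The 26 members outside the noticed genes had a median of 0.38, with 23 above 0 and 4 called higher. They passed camera in limma at the preset correlation and fry (Benjamini-Hochberg adjusted p = 2.45e-06 and 0.00584) but not camera with an estimated correlation (0.126). Without members of the 29 fixed lists too, 24 remained with a median of 0.34 (camera in limma, adjusted p = 0.221 with an estimated correlation). A wider rise of the actin cytoskeleton gene set thus met its criterion, set at the preset correlation, but was not called by camera with an estimated correlation. It stays a hypothesis, which the single siRNA condition leaves open to off-target effects.

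With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 634 changed genes, 269 higher, 365 lower and 631 at least 1.5-fold, in each case the 1 split of 10 with a count as large. The highest other count was 0, with 120 to 1984 genes at an unadjusted p under 0.05 in limma. Each other split mixed control and siP/CAF arrays on both sides, so any group difference widened the spread within a side. The counts of 0 in the other splits are therefore no measure of chance. For gene lists, 3 of the 10 splits called as many as the real 5, and the highest other called 7, with control arrays 1 and 3 and siP/CAF array 2 on one side. The split nearest to the axis of the arrays, with control array 3 and siP/CAF arrays 1 and 2 on one side, called 3.

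Among probes with no gene symbol here, ILMN_1776181 rose by 2.83 and ILMN_1744381 by 2.57 on the log2 scale, and ILMN_3241522 fell by 2.02 and ILMN_3247816 by 2.00.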
